A study of Mus musculus with 5 samples.

How the data were processed

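RNA was measured in cells that the labels give as sorted PMN-MDSCs of wild-type mice, 3 libraries from lung and 2 from tumor. Per the labels' protocols, RNA was extracted with a column kit from at least 2000000 sorted cells, and libraries were made and sequenced on Illumina instruments by a sequencing company. The labels state 20000000 paired reads for each library. They do not state the sort markers, the tumor model, the strain or whether the libraries came from separate animals. Groups were taken from the tissue label and replicate numbers from the sample titles.

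Per the series' design text, the authors quantified transcripts with Salmon 0.9.1 against the transcripts of GENCODE mouse release M24 and deposited TPM, a unit that corrects for transcript length and scales every library to 1000000. Salmon does not align to a genome and divides reads among similar transcripts by a model, so near-identical genes and very short genes have uncertain values. Because TPM is a share, a rise in some transcripts lowers all others. TPM does not keep depth, so no counting error, detection floor or count-based test was possible, and only the spread between libraries gives precision. A value of exactly 0 is reported as listed at 0.

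The deposited table holds 55276 rows, 5 columns of TPM, and 3 columns of the authors' own comparison. Of these rows 20320 were 0 in every library. Of the 55276 rows, 26 carried spreadsheet dates in place of gene symbols, held 0.0650% to 0.0826% of a library's TPM and were left out of all tests. The authors' deposited p-values were recomputed from the TPM columns. All 34956 lay within 0.001 of those from an unequal-variance comparison of group means on untransformed TPM, although the design text speaks of log-transformed values. The second deposited column of p-values is their false discovery rate, adjusted by Benjamini-Hochberg over 34956 rows. The authors' deposited fold changes are natural log values. All 27023 numeric values lay within 0.01 of the natural log of the ratio of mean TPM, tumor over lung, and 5207 cells held a spreadsheet error and 2726 held infinity. These columns were used only to describe the authors' calls.

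Differences between tumor and lung were tested with limma 3.58.1 in R 4.3.3, with an empirical Bayes intensity trend, on log2(TPM + 1) of all 5 libraries. Genes with a mean of at least 1 TPM over the libraries were tested, 16387 in all. Calls needed a Benjamini-Hochberg adjusted p under 0.05 and a difference of at least 1.5-fold, the limits of the design text. Tests were two-sided. Differences are on the log2(TPM + 1) scale, which understates the change of genes with low values, and folds are ratios of mean TPM. The steps were tested on simulated data for the 16387 genes with the spread of these libraries. Of 50 changed genes per size, 2%, 46%, 96% and 92% were recovered at true log2 differences of 1, 2, 4 and 6. Of 126 calls 8 were false, and with no change simulated 0 genes were called. Few genes were changed in the simulation and their noise was independent, whereas 9609 genes passed in the data. With more genes passing, the Benjamini-Hochberg cutoff is looser, so these rates do not carry over to the data.

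Lists of genes were fixed before the data were examined, 33 in all, of which those of other cell types serve as markers only, and no cell type was called from them. Lists with at least 4 tested members were tested with camera from limma at a preset inter-gene correlation of 0.01, adjusted by Benjamini-Hochberg over the lists. Camera with an estimated correlation and fry were run beside it. Lists of pan-leukocyte, hemidesmosome and basement membrane, tight and adherens junction, epithelial-mesenchymal transition and cytosolic ribosomal protein genes, 5 in all, were added after the data had been seen.

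Genes named in the text follow a rule fixed before the data were examined. It takes the 12 largest rises and 12 largest falls among called genes with at least 5 TPM in the higher group and no overlap between groups, up to 4 members with the smallest p in each fixed list, and a fixed set of genes that includes those in the series title. Predicted genes, pseudogenes and immunoglobulin or T cell receptor segments were passed over among the largest changes, 2 among rises and 24 among falls. Some genes that the rule takes are left out of the text. Ptprc, Epcam, Csf3r, Csf1r, Adgre1, Apoe, Mir6236 and the members of the added lists were chosen after their values were seen, as were members named without values to complete a count of 5 or fewer.

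Coordinates are those of GENCODE M21 on GRCm38, matched by symbol, since the M24 annotation was not used here. Of tested symbols 98.5% were found there, and 74.8% of tested genes were protein-coding. Alternatives were pseudocounts of 0.1 and 0.01, no filter and a filter of 5 TPM, 4 rescalings of TPM, limma without trend, robust and unmoderated fits, fold limits of 2 and none, the title number as a replicate block, and leaving out each library, and for the lists the removal of genes that other lists share. Centring on pan-leukocyte genes and restriction to protein-coding genes were added after the data had been seen. Intervals over genes are 95% bootstrap intervals from 10000 draws. Figures were drawn with matplotlib 3.10.9.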

Results

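Transcriptomes were compared between tumor and lung samples of mice that the labels give as polymorphonuclear myeloid-derived suppressor cells (PMN-MDSCs). PMN-MDSCs are neutrophil-lineage cells that restrain T cells and accumulate in tumor-bearing hosts. The series title places the comparison in a study of galectin-1, long-lasting STING activity in the tumor, and the recruitment of these cells during metastasis. The labels give 3 lung libraries (numbers 1, 2 and 3) and 2 tumor libraries (numbers 2 and 3), all wild type, each from at least 2000000 sorted cells and stated as 20000000 paired reads. The markers used for the sort are not given in the sources used here. Values were TPM, length-corrected transcript abundances that sum to 1000000 in each library. TPM keeps no read counts, so the depth behind a gene's value is unknown. Nothing in the labels says whether the libraries came from separate animals, so p-values measure the spread between these libraries, which may be technical. Unless stated otherwise, values are means ± SD (n = 3 lung, n = 2 tumor), differences are log2(TPM + 1) in tumor minus lung with ± SE, and adjusted p-values come from limma.

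The tumor and lung libraries stood far apart, and they differed in transcripts of leukocytes and of epithelia. Ptprc, which encodes the pan-leukocyte surface protein CD45, was at 842, 926 and 959 TPM in the lung libraries and at 18.5 and 75.3 TPM in the tumor libraries. Members of a fixed list of keratins and other epithelial genes summed to between 107 and 167 TPM in lung and to 7276 and 7202 TPM in tumor. Neutrophil identity genes summed to 51809, 60947 and 39630 TPM in lung, against 2953 and 5959 TPM in tumor. The sum includes Ly6c1, a riser at 1495 and 1314 TPM in tumor against 29.8 to 58.2 TPM in lung. The other members therefore fell by more than the sums show. Mitochondrially encoded genes held 2.67% to 4.40% of TPM in lung, and 9.01% and 15.1% in tumor. In tumor mt-Atp8 alone held 49174 and 79331 TPM of this, and the value of so short a gene is uncertain. Pairwise Pearson correlations across genes of log2(TPM + 1) were 0.892 to 0.901 between lung libraries, 0.917 between the tumor libraries and 0.522 to 0.679 between lung and tumor. The first principal component held 74.7% of the variance and separated the tissues. Genes are not independent replicates, and no pair of libraries was identical.

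Of 16387 genes with a mean of at least 1 TPM, 5178 were higher and 4431 lower in tumor, 9609 in all (limma, adjusted p under 0.05 and at least 1.5-fold). A difference of at least 4-fold was found for 1848 of the higher and 1850 of the lower genes. The tumor values lay entirely above or below the lung values for 75.6% of tested genes, where chance gives 20%. A 3 against 2 design has 10 splits, so the smallest exact permutation p for any gene is 0.1. The direction is relative to all transcripts in a library. When libraries were instead centred on 40 pan-leukocyte genes, a choice made after seeing the data that moved the median of all genes from 0.018 to 3.73, 14640 genes were higher and 71 lower. Without tumor replicate 2, 6285 genes passed, with 2831 of them lower.

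The largest rises were in keratins and other genes of epithelia. Krt14, a keratin of basal epithelial cells, was at 2.64 ± 3.37 TPM in lung and 770.2 ± 11.4 TPM in tumor, a difference of 8.12 ± 0.74 (adjusted p = 0.00149). Keratins of simple epithelia followed, with Krt8 at 7.89 ± 5.97 TPM in lung and 1342 ± 105 TPM in tumor (7.48 ± 0.62) and Krt7 at 7.46 ± 4.15 TPM in lung and 1333 ± 96.9 TPM in tumor (7.41 ± 0.42). Krt17 went from 2.12 to 345 TPM (7.18). Cldn4, a tight junction claudin, went from 1.11 to 279 TPM (7.22). Other top rises were S100a14 (1.51 to 288 TPM, 7.26), Msln, which encodes mesothelin (2.44 to 407 TPM, 7.03), Cpe, which encodes carboxypeptidase E (2.71 to 557 TPM, 7.25), Dynap (1.14 to 329 TPM, 7.52), Prl2c2, which encodes a proliferin (0.330 to 283 TPM, 7.73), and Cdkn2a, a cell cycle inhibitor gene (0.646 to 202 TPM, 6.97). Adjusted p-values of these genes lay between 0.000901 and 0.00181. Prl2c2 shares sequence with near-identical neighbours, so its value is uncertain. In GRCm38, by the GENCODE M21 annotation, Krt14 lies on chromosome 11 from 100203162 to 100207548 and Krt8 on chromosome 15 from 101996698 to 102004482, both on the minus strand.

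The largest falls combined neutrophil granule genes, airway and alveolar genes, and short noncoding RNAs. Ngp and Camp, which encode neutrophil granule proteins, were at 1365 ± 665 TPM in lung and 19.3 ± 18.7 TPM in tumor (-6.35 ± 0.78, adjusted p = 0.00257) and at 398 ± 216 TPM in lung and 4.51 ± 4.97 TPM in tumor (-6.39 ± 0.81, adjusted p = 0.00279). Chil3, a chitinase-like protein of neutrophils and alveolar macrophages, fell from 681 to 12.9 TPM (-5.88). Scgb1a1, the secretoglobin of airway club cells, fell from 145 to 0.216 TPM (-6.54), and Sftpc, the surfactant protein of alveolar type II cells, from 50.7 to 0.0301 TPM (-5.55). Rasgrp2, an activator of Rap in blood cells, fell from 311 to 7.81 TPM (-5.50). Bpifa1, a secreted airway protein, was at 268, 19.9 and 25.8 TPM in lung and listed at 0 in both tumor libraries. Mir7087 (93.0, 186 and 243 TPM in lung), Mir150 (11.9, 122 and 70.9 TPM) and the 5S rRNA gene n-R5s207 (36.3, 20.7 and 126 TPM) were also listed at 0 in both tumor libraries. Mir290a and n-R5s54 went from 293 to 11.9 TPM (-5.77) and from 237 to 10.2 TPM (-5.67), differences that were -3.45 and -3.46 without tumor replicate 2. Values of such short or repeated genes are uncertain in a transcript-level quantification. Calls for Bpifa1 and Mir150 ended without either tumor replicate, and those for Mir290a and n-R5s54 when any lung replicate was left out, with adjusted p-values of 0.0625 to 0.0949 and 0.0596 to 0.0873. An unmoderated fit ended the calls of Bpifa1, Mir290a and n-R5s54, a pseudocount of 0.01 those of Mir290a and n-R5s54, and the replicate block that of n-R5s54, with adjusted p-values from 0.0542 to 0.0833.

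Neutrophil genes were lower in tumor as a group, as were genes shared by all leukocytes. Of 20 neutrophil identity genes, 18 fell and 1 rose (18 and 1 adjusted over the list alone), with a median difference of -3.74 (camera adjusted p = 5.23e-06, adjusted p = 0.592 with an estimated correlation). The alarmins S100a8 and S100a9 were at 15436 ± 4014 TPM in lung and 688 ± 586 TPM in tumor (-4.77 ± 0.64, adjusted p = 0.00323) and at 21458 ± 5581 TPM in lung and 1144 ± 869 TPM in tumor (-4.44 ± 0.57, adjusted p = 0.00282). Cxcr2, the neutrophil chemokine receptor, was 18.8-fold lower, at 706 ± 35.1 TPM in lung and 37.7 ± 35.9 TPM in tumor (-4.60 ± 0.67, adjusted p = 0.00398). Ly6g, the surface marker of mouse granulocytes, fell from 288 ± 95.7 to 74.4 ± 17.3 TPM (-1.90 ± 0.32, adjusted p = 0.0062). Its call ended without tumor replicate 2 (adjusted p = 0.062) and with the title number as a replicate block (adjusted p = 0.0594). Trem1 and Fpr1 fell by 4.24 and 4.02, while Padi4, the histone citrullinating enzyme of neutrophils, fell by 1.63. The riser was Ly6c1, a surface protein also made by endothelial and other cells (39.5 to 1405 TPM, 5.18). All 16 endothelial markers fell, however. The similar gene Ly6c2 moved the other way (152 to 16.2 TPM), so the division of reads between these 2 genes is uncertain.

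Granule genes followed the same direction. All but 1 of 16 secondary and tertiary granule genes fell (15 lower and 1 higher, 15 and 1 adjusted over the list alone), with a median of -4.06 (camera adjusted p = 2.16e-05, adjusted p = 0.592 with an estimated correlation). Lcn2, which encodes lipocalin-2, fell from 1217 to 73.9 TPM and Dhrs7 from 107 to 15.0 TPM, whereas Anxa1, which encodes annexin A1, rose from 553 to 2105 TPM. Of 6 tested primary granule and precursor genes, 4 fell and 1 rose (4 and 1 adjusted over the list alone). Among them Mgst1 fell from 132 to 12.6 TPM, Cebpe from 12.2 to 1.21 TPM and Fcnb from 5.93 to 0.235 TPM, and Cd63, a lysosomal and exosomal tetraspanin, rose from 66.4 to 647 TPM. The fallers were Prtn3, Fcnb, Cebpe and Mgst1. That list did not pass camera (median -2.27, camera adjusted p = 0.124). Camera called it lower with no filter on low values (median -0.97, adjusted p = 0.00578) and in protein-coding genes (adjusted p = 0.0274). Fry called it lower in the main setting (fry adjusted p = 0.0123).

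The 40 pan-leukocyte genes, listed after the data were seen, give the level against which the leukocyte lists can be read. In tumor 39 of them were lower and 0 higher, with a median of -3.51 (camera adjusted p = 5.03e-13, adjusted p = 0.358 with an estimated correlation). Relative to that median, neutrophil identity genes stood at -0.23 and secondary and tertiary granule genes at -0.56.

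**Figure D1:**
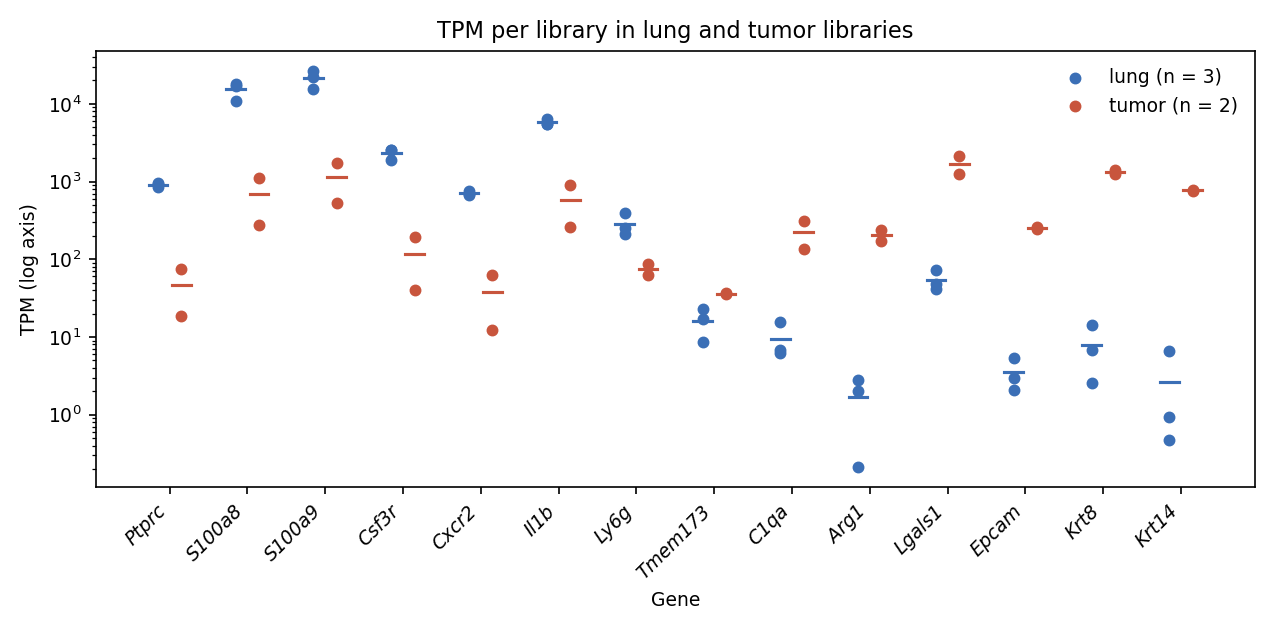
TPM of 14 genes in each library, on a log axis, with lung libraries (n = 3) in blue and tumor libraries (n = 2) in red, and short bars for group means. Ptprc lies at 842 to 959 TPM in lung and at 18.5 and 75.3 TPM in tumor, and Krt14, Krt8 and Epcam lie higher in both tumor libraries than in any lung library.

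Suppressive effector genes of MDSCs did not move together. Arg1, the arginase that depletes arginine, rose from 1.67 ± 1.32 to 206 ± 46.5 TPM (6.41 ± 0.54, adjusted p = 0.00132), while Arg2, the mitochondrial arginase, fell from 159 ± 22.9 to 14.5 ± 11.2 TPM (-3.57 ± 0.50, adjusted p = 0.00354). Nos2, the inducible nitric oxide synthase, was at 5.07 ± 1.65 against 6.48 ± 2.15 TPM (adjusted p = 0.436). Cd274, which encodes PD-L1, was at 27.6 ± 1.89 against 21.3 ± 14.7 TPM (adjusted p = 0.345), with tumor values of 10.9 and 31.7 TPM. Without tumor replicate 3 it passed as lower (-1.26, adjusted p = 0.0145), and without tumor replicate 2 its difference was 0.20 (adjusted p = 0.352). Ptgs2, the inducible cyclooxygenase, fell from 550.2 ± 42.4 to 127 ± 55.7 TPM (-2.17 ± 0.30, adjusted p = 0.00348). Of 27 tested members of the MDSC list, 19 fell and 4 rose (19 and 4 adjusted over the list alone), with a median of -2.77 (camera adjusted p = 0.0011, adjusted p = 0.592 with an estimated correlation), or 0.73 relative to the pan-leukocyte median. The risers were Arg1, Ptges, Tnfrsf10b and Nt5e, in the libraries with the higher epithelial sums and lower Ptprc given above. Their source among the cells was not tested. The NADPH oxidase subunit gene Ncf4 fell from 265 to 31.1 TPM, the transcription factor gene Cebpb from 1069.9 to 154 TPM and Stat3 from 429 to 116 TPM.

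Inflammatory genes and chemokine ligands went both ways. Il1b fell from 5762 ± 572 to 579 ± 451 TPM (-3.57 ± 0.54, adjusted p = 0.0044) and Cxcl2, a neutrophil attractant, from 1922 ± 119 to 463 ± 222 TPM (-2.14 ± 0.33, adjusted p = 0.00458). Of 35 NF-kB targets and inflammatory cytokines, 17 fell and 6 rose (17 and 6 adjusted over the list alone), with a median of -0.96, or 2.55 relative to the pan-leukocyte median (camera adjusted p = 0.014, adjusted p = 0.604 with an estimated correlation). Without tumor replicate 2 that median was -0.47 (adjusted p = 0.0493). Birc3 (574 to 28.8 TPM), Tnfaip2 (938 to 106 TPM), Rel (24.5 to 2.89 TPM) and Bcl3 (129.7 to 29.98 TPM) fell. Among 22 chemokine ligands 12 rose and 5 fell (12 and 5 adjusted over the list alone), and the list as a whole did not pass (median 1.33, camera adjusted p = 0.164). It passed as higher with no filter on low values (adjusted p = 0.0292) and in genes of at least 5 TPM (median 2.26, adjusted p = 0.0355). Fry called it higher in the main setting (fry adjusted p = 0.0162). Risers were Cxcl5, a neutrophil-attracting chemokine of epithelial cells (0.502 to 45.5 TPM, 4.96), Cxcl16 (2.60 to 46.4 TPM), Cxcl14 (1.30 to 14.2 TPM) and Ccl12 (0.189 to 9.96 TPM). Lower ligands were Ccl6, Ccl22, Cxcl2, Cxcl12 and Cxcl13. Chemoattractant receptors were lower for 18 of 22 genes and higher for 3 (18 and 3 adjusted over the list alone), with a median of -2.87 (camera adjusted p = 0.000132, adjusted p = 0.592 with an estimated correlation). Higher receptors included Ackr3 and C3ar1. Falls were found for Cxcr1 (48.1 to 2.48 TPM), Cxcr5, a receptor of follicular B cells (18.0 to 0.540 TPM), and the sphingosine-1-phosphate receptor genes S1pr1 (29.3 to 2.04 TPM) and S1pr4 (14.8 to 0.290 TPM).

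Galectin-1 and STING, which the series title names, were both measured. Lgals1, which encodes galectin-1, rose 31.3-fold, from 53.9 ± 16.5 to 1686 ± 589 TPM (4.94 ± 0.34, adjusted p = 0.00108), in the libraries with the higher epithelial sums. Among 7 tested galectin genes 3 rose and 1 fell (3 and 1 adjusted over the list alone). Lgals7, a galectin of stratified epithelia (0.0913 to 26.7 TPM), and Lgals3bp (19.3 to 38.6 TPM) rose, and Lgals9 fell (89.1 to 27.7 TPM). The Lgals3bp call ended without either tumor replicate (adjusted p = 0.0602 and adjusted p = 0.0926). The list median of -0.0035, the mean of 1.02 and the upward set test (camera adjusted p = 0.775) differed in sign. Fry called the list higher (fry adjusted p = 0.00357). The sign of the median depended on single libraries, at 0.087, 0.044 and -0.14 without lung replicates 1, 2 and 3. Tmem173, the symbol the files use for STING, was at 16.2 ± 7.28 against 36.2 ± 0.216 TPM (1.21 ± 0.42) and just missed the threshold (adjusted p = 0.0549). It passed under 7 of the alternative settings, with adjusted p-values from 0.0258 to 0.0449. Cgas, the DNA sensor upstream of STING, was near the 1 TPM filter, at 1.33 ± 0.302 against 0.896 ± 0.147 TPM (adjusted p = 0.408). Lgals1 lies on chromosome 15 from 78926725 to 78930465 and Tmem173 on chromosome 18 from 35733679 to 35740554 (GRCm38, GENCODE M21).

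Interferon-stimulated genes were lower in tumor. Of 45 tested members of the type I interferon list, 37 fell and 2 rose (38 and 2 adjusted over the list alone), with a median of -1.88 (camera adjusted p = 7.08e-09, adjusted p = 0.592 with an estimated correlation). The risers were Bst2 and Ifi205. Relative to the pan-leukocyte median the list stood at 1.63, on the other side of 0. Cmpk2 fell from 26.5 to 1.97 TPM, Ddx60 from 24.5 to 1.60 TPM and Ifit3 from 20.1 to 3.47 TPM, and Ifit3 has a near-identical copy that makes its value uncertain. Ifnb1, the interferon-beta gene, was listed at 0 in every library. The cGAS-STING list had 7 lower and 2 higher genes among 16 (6 and 2 adjusted over the list alone). It did not pass camera (median -0.21, camera adjusted p = 0.272), but fry called it lower (fry adjusted p = 0.0353). Its higher genes were Enpp1 and Trim32. The nucleotide-hydrolysing enzyme gene Samhd1 fell from 676 to 69.0 TPM, the exonuclease gene Trex1 from 35.1 to 8.505 TPM and the interferon receptor gene Ifnar2 from 55.1 to 24.3 TPM, while the ubiquitin ligase gene Trim32 rose from 1.46 to 11.6 TPM.

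Cell cycle genes rose without exception. All 30 members were higher (30 adjusted over the list alone), with a median of 2.56 (camera adjusted p = 1.53e-09, adjusted p = 0.592 with an estimated correlation). Top2a, the topoisomerase of dividing cells, rose from 6.65 ± 1.52 to 86.4 ± 18.2 TPM (3.52 ± 0.26, adjusted p = 0.00115), the cyclin gene Ccnb1 from 2.22 to 38.9 TPM, the thymidylate synthase gene Tyms from 2.94 to 34.1 TPM and Stmn1 from 15.0 to 83.7 TPM. Epithelial markers were higher in the same libraries, as given above. Nuclear genes of oxidative phosphorylation also rose, with 30 of 39 higher and 0 lower (31 and 0 adjusted over the list alone) and a median of 1.06 (camera adjusted p = 5.23e-06, adjusted p = 0.592 with an estimated correlation). Examples were the ATP synthase genes Atp5b (734 to 1950.0 TPM) and Atp5o (36.2 to 126 TPM), Ndufa4 (36.5 to 119 TPM) and Sdhc (31.4 to 90.0 TPM). Mitochondrially encoded members were higher for 8 of 13 and lower for 0 (8 and 0 adjusted over the list alone), with a median of 1.47 (camera adjusted p = 0.00597, adjusted p = 0.592 with an estimated correlation). In this list mt-Atp8, a short gene of uncertain value that overlaps mt-Atp6, rose from 14232 to 64253 TPM. Also higher were mt-Co1 (2432 to 10001 TPM), mt-Co3 (1565 to 6775 TPM) and mt-Atp6 (915 to 2948 TPM). Without tumor replicate 3 the mitochondrially encoded list no longer passed (adjusted p = 0.0665), nor did those 4 genes, with adjusted p-values from 0.0639 to 0.206. With the title number as a replicate block those 4 genes did not pass either, with adjusted p-values from 0.0714 to 0.0789. Leaving out any other library, or no filter on low values, also ended the mt-Atp8 call, tumor replicate 2 the mt-Atp6 call and lung replicate 3 the mt-Co1 call.

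Hypoxia and glycolysis genes were higher, with larger adjusted p-values in the set test. Vegfa, the endothelial growth factor gene, rose from 34.7 ± 4.01 to 103 ± 3.56 TPM (1.55 ± 0.16, adjusted p = 0.0018). Of 28 hypoxia genes 18 rose and 4 fell (18 and 4 adjusted over the list alone), with a median of 1.21 (camera adjusted p = 0.0332, adjusted p = 0.592 with an estimated correlation). The collagen-modifying enzyme genes Plod2 (0.332 to 22.8 TPM) and P4ha2 (2.33 to 30.2 TPM) and the adenylate kinase gene Ak4 (0.399 to 13.3 TPM) rose, and Pfkfb4 fell (241 to 14.7 TPM). The lower hypoxia genes were Slc16a3, Hif1a, Pfkfb3 and Pfkfb4. Of 22 glycolysis genes 12 rose and 4 fell (13 and 4 adjusted over the list alone), with a median of 0.84 (camera adjusted p = 0.0413, adjusted p = 0.592 with an estimated correlation). The lactate transporter gene Slc16a1 (1.40 to 32.6 TPM), the phosphofructokinase genes Pfkl (38.2 to 121 TPM) and Pfkm (2.33 to 16.3 TPM) and Aldoc (7.19 to 29.6 TPM) rose. The lower glycolysis genes were Slc2a3, Hk3, Pfkfb3 and Slc16a3. These libraries also held the higher epithelial sums given above. The hypoxia call was lost without lung replicate 3 or tumor replicate 3 (adjusted p = 0.0508 and adjusted p = 0.0533), in genes of at least 5 TPM (adjusted p = 0.0747) and in protein-coding genes (adjusted p = 0.0904). The glycolysis call was lost in those 4 settings, without lung replicate 1, without tumor replicate 2 and with a common median ratio, with adjusted p-values from 0.0528 to 0.158.

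Stress, lipid and matrix genes went both ways, and their lists did not pass camera, although some did under other settings. Fry called the matrix and angiogenesis list and the stress response list higher (fry adjusted p = 0.000374 and 0.0123). In the unfolded protein and integrated stress response 12 of 26 genes rose and 8 fell (12 and 8 adjusted over the list alone; median 0.59, camera adjusted p = 0.485). The stress regulator Nupr1 (6.51 to 108 TPM) and the secreted factor Manf (48.5 to 232 TPM) rose, and Chac1 (37.8 to 3.20 TPM) and Herpud1 (65.8 to 22.8 TPM) fell. Of 30 lipid and eicosanoid genes 10 rose and 15 fell (10 and 15 adjusted over the list alone; median -1.02, camera adjusted p = 0.173), and the list passed as lower in protein-coding genes (adjusted p = 0.0391). Alox5, the leukotriene-forming lipoxygenase, fell from 159 to 7.02 TPM and the nuclear receptor gene Pparg from 13.1 to 0.527 TPM, while the desaturase gene Scd2 rose from 8.78 to 141 TPM and Acsl3 from 1.77 to 18.5 TPM. Among 28 matrix and angiogenesis genes 14 rose and 8 fell (14 and 8 adjusted over the list alone; median 0.73, camera adjusted p = 0.164), and the list passed as higher with no filter on low values (adjusted p = 0.0144). The membrane protease gene Mmp14 rose from 2.94 ± 1.05 to 174 ± 22.3 TPM (5.50 ± 0.26, adjusted p = 0.000901), the urokinase gene Plau from 2.33 to 112 TPM, the growth factor gene Hbegf from 1.43 to 50.3 TPM and the fibronectin gene Fn1 from 85.9 to 1341 TPM, in the libraries with the higher epithelial sums. Immediate early and heat shock genes, a list for handling during cell isolation, had 8 higher and 15 lower members among 30 (8 and 15 adjusted over the list alone; median -1.35, camera adjusted p = 0.0873). The heat shock genes Hspa1b (6.36 to 103 TPM), Hspa1a (6.00 to 46.3 TPM) and Hsp90aa1 (265 to 999.8 TPM) rose, and Nr4a1, an early response gene, fell (329 to 35.3 TPM). The median of that list was -0.78 without tumor replicate 2, and it passed as lower without tumor replicate 3 (adjusted p = 0.0333) and in protein-coding genes (adjusted p = 0.0163).

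Antigen presentation genes were lower. Of 16 MHC class I presentation genes 14 fell and 0 rose (14 and 0 adjusted over the list alone), with a median of -2.16 (camera adjusted p = 5.23e-06, adjusted p = 0.592 with an estimated correlation), or 1.35 relative to the pan-leukocyte median. The class I heavy chain gene H2-D1 fell from 1474 ± 120.1 to 205 ± 67.0 TPM (-2.87 ± 0.25, adjusted p = 0.00136), the peptide transporter genes Tap1 from 77.8 to 10.6 TPM and Tap2 from 95.4 to 16.5 TPM, and the regulator Nlrc5 from 14.9 to 2.28 TPM. Class I heavy chains are near-identical paralogs, so the H2-D1 value is uncertain. Of 14 MHC class II and costimulation genes 7 fell and 0 rose (4 and 0 adjusted over the list alone), with a median of -1.07 (camera adjusted p = 0.0108, adjusted p = 0.592 with an estimated correlation), or 2.44 relative to the pan-leukocyte median. H2-Ob (25.3 to 0.546 TPM), H2-DMb2 (24.4 to 2.84 TPM), H2-Oa (5.24 to 0.251 TPM) and Cd80 (32.4 to 8.61 TPM) fell, of which H2-Ob and H2-Oa encode the B cell peptide-loading modulator H2-O. Without tumor replicate 2 neither the class II list (median -0.47, adjusted p = 0.0877) nor H2-Oa (adjusted p = 0.0514) passed, and Cd80 did not pass with the title number as a replicate block (adjusted p = 0.0521).

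Marker lists for other cells that lung or tumor tissue could contribute moved in different directions. Keratins and other epithelial markers rose for 16 of 18 genes, and 0 fell (16 and 0 adjusted over the list alone), with a median of 5.74 (camera adjusted p = 6.01e-07, adjusted p = 0.592 with an estimated correlation). Krt19 rose from 39.8 ± 9.36 to 1342 ± 42.7 TPM, Krt18 from 5.38 ± 2.63 to 632 ± 36.5 TPM and Krt6a from 0.262 ± 0.358 to 58.3 ± 2.56 TPM. Alveolar and airway epithelial markers moved the other way, with 9 lower and 1 higher among 14 (10 and 1 adjusted over the list alone) and a median of -3.31 (camera adjusted p = 0.0025, adjusted p = 0.592 with an estimated correlation). Napsa fell from 119.5 to 6.50 TPM and Ager from 6.29 to 0.247 TPM, and the higher gene was Aqp5. All 16 endothelial markers fell (16 adjusted over the list alone), with a median of -3.19 (camera adjusted p = 3.72e-06, adjusted p = 0.592 with an estimated correlation), including Cldn5 (77.3 to 1.78 TPM), Cdh5 (36.7 to 1.61 TPM), Vwf (34.8 to 2.10 TPM) and Tek (14.6 to 0.251 TPM). All 17 B and plasma cell markers fell (17 adjusted over the list alone), with a median of -3.89 (camera adjusted p = 1.62e-06, adjusted p = 0.592 with an estimated correlation), including Igkc (236 to 2.81 TPM), Cd79a (73.0 to 1.71 TPM), Ms4a1 (24.6 to 0.358 TPM) and Ighd (24.03 to 0.240 TPM). Alveolar macrophage markers fell for 11 of 13 genes and rose for 0 (11 and 0 adjusted over the list alone), with a median of -3.71 (camera adjusted p = 6.36e-05, adjusted p = 0.592 with an estimated correlation). Marco fell from 24.7 to 0.289 TPM, Krt79 from 53.1 to 2.83 TPM and Fabp1 from 18.2 to 0.161 TPM.

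The remaining marker lists were mixed and did not pass camera, apart from the settings named below. Fry called the T and NK cell list and the eosinophil, basophil and mast cell list lower (fry adjusted p = 0.0123 and 0.0194). Macrophage and monocyte markers rose for 8 and fell for 5 of 21 genes (8 and 5 adjusted over the list alone; median 0.17, camera adjusted p = 0.801), and the median was -0.26 without tumor replicate 3. The complement genes C1qa (9.52 ± 5.26 against 223 ± 121 TPM) and C1qb (9.50 ± 3.69 against 168 ± 86.1 TPM) and Ms4a7 (0.702 to 14.7 TPM) rose, and Ly6c2, a marker of inflammatory monocytes, fell (152 to 16.2 TPM). The lower macrophage and monocyte genes were Adgre1, Csf1r, Cd68, Ly6c2 and Ccr2. Fibroblast and mural markers rose for 9 and fell for 2 of 16 (9 and 2 adjusted over the list alone; median 1.61, camera adjusted p = 0.124). The list passed as higher with no filter on low values (adjusted p = 0.0133), in genes of at least 5 TPM (median 2.71, adjusted p = 0.0453) and without tumor replicate 3 (median 2.19, adjusted p = 0.017). The collagen gene Col3a1 (9.37 ± 3.15 against 538 ± 536 TPM) and Sparc (16.8 ± 6.74 against 692 ± 484 TPM) rose, with wide SDs between the tumor libraries (list median 1.04 without tumor replicate 2), and Acta2 (8.90 to 1.37 TPM) and Inmt (5.14 to 0.213 TPM) fell. T and NK cell markers were low in every library and fell for 6 and rose for 1 of 11 (6 and 1 adjusted over the list alone; median -1.38, camera adjusted p = 0.0624). Lck (3.09 to 0.155 TPM), Gzma (4.48 to 0.435 TPM) and Trbc2 (2.33 to 0.0626 TPM) fell and Skap1 (0.913 to 10.0 TPM) rose. The T and NK cell list passed as lower under 8 of the alternative settings, with adjusted p-values from 0.000585 to 0.0443. Its median was -2.999 and -3.47 at pseudocounts of 0.1 and 0.01, since log2(TPM + 1) limits the falls of genes of a few TPM. Dendritic cell markers rose for 3 and fell for 4 of 13 (3 and 4 adjusted over the list alone; median -0.51, camera adjusted p = 0.465). The median was 1.54 with only genes of at least 5 TPM and -0.31 without tumor replicate 2. The actin-bundling gene Fscn1 (13.3 to 201 TPM) and Cacnb3 (2.27 to 31.2 TPM) rose, and Ccr7 (16.4 to 1.54 TPM) and Ly6d (38.7 to 2.27 TPM) fell. Higher dendritic cell genes were Bst2, Fscn1 and Cacnb3, and lower ones Clec9a, Ccr7, Ccl22 and Ly6d.

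Eosinophil, basophil and mast cell markers fell for 7 and rose for 2 of 13 genes (7 and 2 adjusted over the list alone; median -1.83, camera adjusted p = 0.182). Kit (24.7 to 1.37 TPM), Gata2 (22.1 to 1.34 TPM) and Prg2 (7.92 to 0.577 TPM) fell and Il5ra (1.32 to 34.1 TPM) rose, the other riser being Tpsb2. Platelet markers rose for 2 and fell for 3 of 7 (2 and 4 adjusted over the list alone; median -1.08, camera adjusted p = 0.398). The platelet chemokine genes Pf4 (7.14 to 105 TPM) and Ppbp (6.15 to 48.5 TPM), which macrophages can also express, rose, and Clec1b (5.15 to 0.177 TPM) and Tubb1 (3.14 to 0.169 TPM) fell, as did Gp9. Of 6 erythroid genes 1 passed, the metabolic enzyme gene Bpgm (2.81 to 8.47 TPM, adjusted p = 0.0497), and 0 passed adjusted over the list alone (median -1.35, camera adjusted p = 0.272). The hemoglobin genes Hbb-bs (283 ± 175 against 98.0 ± 16.1 TPM), Hba-a1 (81.4 ± 45.8 against 27.5 ± 0.321 TPM) and Hbb-bt (25.6 ± 19.5 against 7.42 ± 0.127 TPM) did not pass, with adjusted p-values from 0.053 to 0.1. Under alternative settings Hba-a1 passed as lower in 6, with adjusted p-values from 0.017 to 0.0493, Hbb-bs in 3, from 0.0327 to 0.038, and Hbb-bt in 1, protein-coding genes (0.0403). Without lung replicate 2 the differences of Hbb-bs and Hbb-bt went from -1.34 to -0.87 and from -1.41 to -0.85, and the erythroid median to -0.85. They are near-identical paralogs, so their separate values are uncertain. Bpgm lost its call under 12 of the alternative settings, including without tumor replicate 2 (adjusted p = 0.257).

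**Figure D2:**
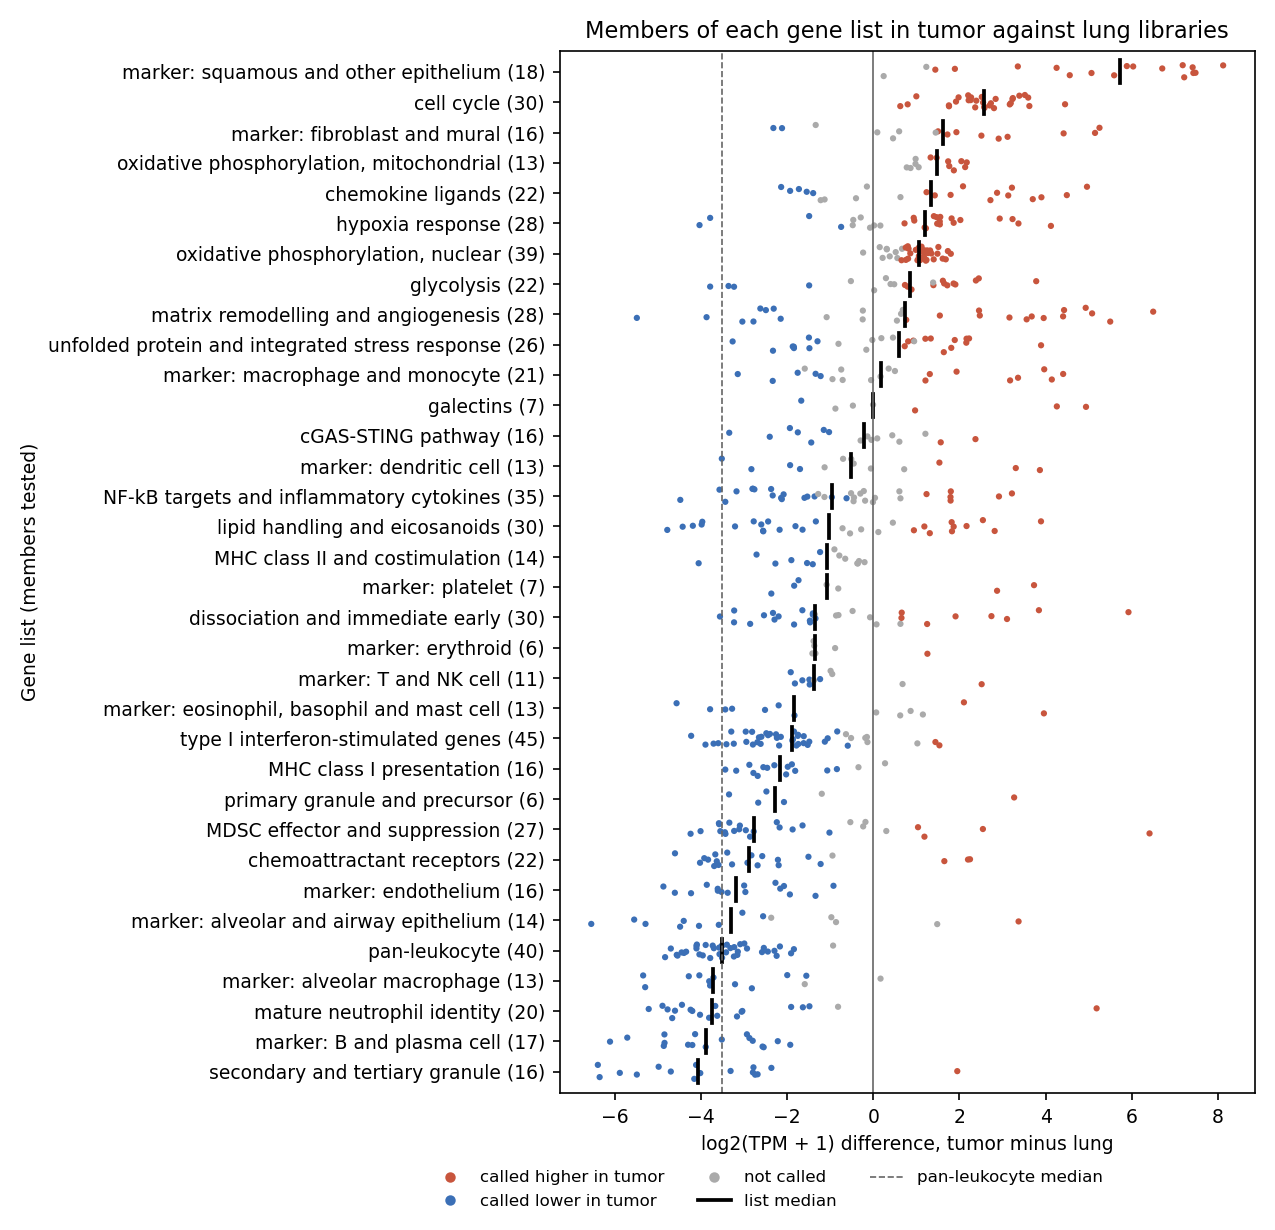
Differences in log2(TPM + 1), tumor minus lung, for each tested member (points) of the 33 fixed lists and the pan-leukocyte list, ordered by list median (black bars), with members called higher in red, lower in blue and not called in grey. The dashed line marks the pan-leukocyte median of -3.51, next to which the neutrophil identity (-3.74), alveolar macrophage (-3.71) and B cell (-3.89) medians lie, and the epithelial list has the highest median, 5.74. For the B cell list this holds only at the pseudocount of 1 shown. At pseudocounts of 0.1 and 0.01 it stood -1.38 and -2.33 from the pan-leukocyte median.

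Camera called 18 of the 33 fixed lists with its preset correlation, 6 higher and 12 lower, and none with correlations estimated from these 5 libraries, where the smallest adjusted p was 0.592 and 0 lists had an unadjusted p under 0.05. The rotation test fry, which asks whether a list's genes move, on balance, one way, called 23. Of the lists that camera called, fry did not call NF-kB targets, MHC class II or mitochondrially encoded oxidative phosphorylation (fry adjusted p = 0.0692, 0.096 and 0.0565). It called the matrix, galectin, stress response, primary granule, T and NK cell, chemokine ligand, eosinophil and cGAS-STING lists, which camera did not (fry adjusted p from 0.000374 to 0.0353).

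The authors' deposited table gives its own comparison of the same libraries, and it calls far fewer genes. A total of 223 genes in the authors' deposited table had a false discovery rate under 0.05, of which 220 also differed at least 1.5-fold, 162 higher and 58 lower in tumor, and 8040 had an unadjusted p under 0.05. Of those 220 genes 196 were tested here, and all 196 were called in the same direction. Its natural log fold changes and the limma differences had a Spearman correlation of 0.973 across genes, which are not independent replicates. Genes the authors' deposited table called higher had a median coefficient of variation of 1.49% between the tumor libraries, against 14.3% for genes called higher by limma. Of 20 members of the epithelial list, the authors' deposited table called 1, Krt17, and of 36 neutrophil identity and granule genes it called 1, Chil3. In the authors' deposited table the false discovery rates of Lgals1, Arg1, Krt14 and S100a8 were 0.360, 0.291, 0.0912 and 0.157.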

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

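Centring on pan-leukocyte genes and restriction to protein-coding genes were chosen after seeing the data, and all other settings before. Across the planned settings that kept all libraries, between 7082 and 10148 genes were called, against 9609. The share of higher genes stayed between 51.5% and 59.6%. The number of tested genes differed too. The 7082 were of 10772 with the filter of 5 TPM, the 10148 of 17758 without the 20 top genes, and the 9609 of 16387. Leaving out each replicate gave 6285 to 8848 genes, with 3454 to 4669 higher and 2831 to 4179 lower, the lowest of each without tumor replicate 2. There the lone tumor library is assumed to vary like the lung libraries, and the larger SE follows from fewer samples. That library, tumor replicate 3, also stood closer to lung, with a pan-leukocyte median difference of -2.85 against -4.16 in tumor replicate 2. Centred on pan-leukocyte genes, 14711 genes were called, 14640 higher (99.5%) and 71 lower, by construction, since it raises every tumor value, with the median difference of all genes at 3.73 in place of 0.018. Protein-coding genes alone gave 8805 of 12892 tested genes, 61.1% higher, with that median at 0.38, and it was 0.19 without mitochondrial, ribosomal protein and hemoglobin genes. Under the other scalings it lay between -0.027 and 0.074.

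The title numbers 2 and 3 are shared by lung and tumor, but the labels do not say what they mark. Deviations of same-numbered libraries from their group means correlated at 0.0034 and 0.083 across genes. With only 2 tumor libraries, their deviations are mirror images of each other. These values therefore cannot show or exclude that same-numbered libraries share more than a number. With the number as a replicate block 7111 genes were called, 3662 higher and 3449 lower.

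Camera called 16 to 23 of the 33 lists in all settings run with the preset correlation, against 18, and 0 lists, 0 higher and 0 lower, with an estimated correlation, where 0 lists had an unadjusted p under 0.05, while fry called 23. The cause of that loss was not tested. Camera was not run for the robust and unmoderated fits, for which it has no setting, nor for centring on pan-leukocyte genes. The direction reversed for the dendritic cell list with genes of at least 5 TPM (median 1.54, fewer genes), for the macrophage and monocyte list in protein-coding genes (test lower, median 0.19) and without tumor replicate 3 (leave-out medians -0.26 to 0.72), and for Cd274 without tumor replicate 2 (leave-out differences -1.26 to 0.20), and the cause was not tested. None of these was called in the main test. Across 164 tested named genes and the settings run for single genes, which do not include the fold limits or centring on pan-leukocyte genes, 2850 results kept direction and side of the threshold, 49 lost the call, 18 gained it and 1 reversed. For the lists these numbers were 455, 13, 19 and 3. Smaller pseudocounts enlarge the differences of genes with low values by construction. At a pseudocount of 0.01 the medians of the primary granule, T and NK cell, and eosinophil, basophil and mast cell lists stood 0.014, 0.13 and -0.20 from the pan-leukocyte median, against 1.23, 2.13 and 1.68 at a pseudocount of 1, a comparison chosen after seeing the data. Other medians came to lie further below it. B and plasma cell markers stood at -2.33 against -0.38, alveolar and airway epithelium at -1.92 against 0.20, and endothelium at -0.63 against 0.32. Depth is not recorded in TPM, so what it limits could not be tested.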

Other observations

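The tests in this part, and the gene lists they use, were chosen after the results had been seen, except the fixed epithelial, neutrophil, macrophage and interferon lists.

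Genes that anchor epithelia to basement membrane and to each other were higher in the tumor libraries. Of 19 hemidesmosome and basement membrane genes 17 rose and 1 fell, with a median of 3.56 (camera adjusted p = 2.99e-07, adjusted p = 0.22 with an estimated correlation). The integrin genes Itgb4 (1.46 to 191 TPM) and Itga6 (12.4 to 325 TPM) and the collagen gene Col18a1 (1.90 to 274 TPM) rose, and Nid1 fell (3.26 to 1.28 TPM). Of 19 tight and adherens junction genes 17 rose and 0 fell, with a median of 2.64 (camera adjusted p = 4.49e-07, adjusted p = 0.22 with an estimated correlation). Cldn6 rose from 0.893 to 194 TPM, Cldn3 from 2.25 to 178 TPM and the splicing factor gene Esrp1, specific to epithelia, from 0.187 to 19.1 TPM. Genes of the epithelial-mesenchymal transition were higher for 12 and lower for 2 of 18 (median 3.21, camera adjusted p = 0.00591, adjusted p = 0.358 with an estimated correlation), and the median was 1.90 in tumor replicate 3 alone, without tumor replicate 2. Fibroblast and mural markers differed in the same way between the tumor libraries, with medians of 2.19 in replicate 2 and 1.04 in replicate 3, and Col3a1 was at 917 and 159 TPM there. Tpm1 (8.29 to 321 TPM) and Twist1 (0.0825 to 12.5 TPM) rose and Snai1 and Tgfbi fell (Snai1 24.4 to 8.42 TPM), while Vim, abundant in leukocytes too, was at 1869 ± 279.6 against 2925 ± 1100.3 TPM (adjusted p = 0.135).

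Cytosolic ribosomal protein genes rose for 35 of 40 and fell for 0, with a median of 1.33 (camera adjusted p = 1.85e-07, adjusted p = 0.365 with an estimated correlation). Rps2 was the member with the largest difference, from 329 ± 52.3 to 1841 ± 475 TPM. These genes rose in the libraries in which epithelial genes rose and pan-leukocyte genes fell (median -3.51). Mir6236, a short gene, held 74350 to 96565 TPM in every library, and mt-Atp8 held 9994 to 16578 TPM in lung and 49174 and 79331 TPM in tumor.

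Neutrophil identity and granule genes were lower in tumor, with a median of -3.91 over 36 genes (95% bootstrap interval over genes -4.24 to -3.05). Their median lay only -0.41 from that of the 40 pan-leukocyte genes (interval -0.92 to 0.47). Those 40 genes were listed after the data were seen. This difference therefore cannot decide whether loss of neutrophil genes inside leukocytes is the whole cause. A few genes taking most of the TPM is argued against. The share of TPM outside the 20 most abundant genes was lower in tumor by a log2 ratio of only -0.12 (-0.16 to -0.071 over pairs of libraries), far from the fall of the neutrophil genes. RNA of cells that are not leukocytes making up most of the tumor libraries is a candidate explanation. The pan-leukocyte median was -3.51 (interval -3.75 to -3.19). That of 18 epithelial genes, none shared with another fixed list, was 5.74 (interval 3.80 to 7.20), with Krt19 and Krt8 both at 1342 TPM in tumor. These intervals are over genes, not over libraries. The pan-leukocyte medians of tumor replicates 2 and 3, -4.16 and -2.85, both lay outside the first interval. A sort for PMN-MDSCs would be meant to remove cells that are not leukocytes. Alveolar, endothelial and B cell markers were higher in the lung libraries, so each tissue may have brought its own other cells. A change of PMN-MDSCs between tissues as the whole cause is argued against by the epithelial values. It would not by itself raise 16 of 18 epithelial genes, a list fixed before the data were examined. The fall of 39 of 40 pan-leukocyte genes adds little, since that list was made after the data were seen. A change of PMN-MDSCs as a part of the cause stays open and untested, as does a difference in the gate or cell recovery between tissues.

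Macrophage and monocyte genes were not lower as a list, with a median of 0.17 (0.72 without tumor replicate 2 and -0.26 without tumor replicate 3), which is 3.68 above that of the pan-leukocyte genes (interval 2.42 to 4.95), or 3.77 above it at a pseudocount of 0.01. The dendritic cell list was not called lower in the report's test either, and stood 2.995 above it (2.62 at a pseudocount of 0.01). A larger share of macrophages among the leukocytes of the tumor libraries is a candidate explanation. Csf1r (-2.33) and Adgre1 (-1.75) fell by less than the pan-leukocyte median of -3.51, but alveolar macrophage markers stood at -0.20 on the same scale (-0.79 at a pseudocount of 0.01). Among the fixed lists, only the neutrophil identity, secondary and tertiary granule, alveolar macrophage, and B and plasma cell lists stood below that median at a pseudocount of 1. Standing above it therefore cannot single out the macrophage share. Of the 21 genes 5 are in other fixed lists, and cells that are not leukocytes may also express some of them, such as Apoe, at 1169.6 TPM in tumor. A different macrophage state in tumor, with no change in their share, stays open and was not tested.

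Interferon-stimulated genes were lower in tumor but stood 1.63 above the pan-leukocyte median (interval 0.92 to 1.92), or 1.19 above it at a pseudocount of 0.01 (interval 0.65 to 1.81). The lower level of leukocyte RNA may account for the fall. Most other fixed lists with a negative median also stood above the pan-leukocyte median, such as MHC class I presentation (1.35). Standing above it therefore cannot decide this. Whether the response per leukocyte differs between tumor and lung stays open, since other cells express these genes as well. Lgals1, the galectin-1 gene, rose to 1686 TPM in the same libraries in which epithelial genes rose. There 9 of 16 fibroblast and mural markers rose too, and 2 fell. Lgals1 was at 2102 and 1269 TPM in tumor replicates 2 and 3, with fibroblast and mural medians of 2.19 and 1.04 and epithelial medians of 5.73 and 5.75. The source of Lgals1 among the cells was not tested.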
